A study of Mus musculus with 2 samples.

How the data were processed

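Tumour cell suspensions from 1 shCtrl and 1 shSrsf10 group of mice were profiled by droplet single-cell RNA sequencing. The labels describe the libraries in conflicting ways. The series design names the 10x 5' kit, digestion of the tumours and a flow cytometry sort whose gate is not stated. The sample protocol names the 10x 3' version 3 kit and a slow spin of a liver suspension that leaves most hepatocytes behind. Which of these was used could not be settled from the labels. The submitters' processing notes name Cell Ranger 6.1.0 and genome build mm10. The deposited files hold whole-number UMI counts per gene and barcode, not normalized, for 32285 features. The barcodes are 17 bases long, where 10x barcodes have 16, and the lowest total per barcode in both files is 500 UMIs, so a filter by the authors before deposition is possible but not stated. No reads were available, so splicing was not analysed here.

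The shCtrl file held 9920 barcodes and 143327661 UMIs, and the shSrsf10 file 7553 barcodes and 136419902 UMIs. The median depth was 11972.5 and 11167 UMIs and 2392 and 2299 genes per barcode. Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. The mitochondrial limit removed more in shCtrl, where 3.78% of barcodes exceeded it against 0.847% in shSrsf10. The barcodes with the highest Scrublet doublet scores were removed from each library, at 0.8% per 1000 barcodes, 775 in shCtrl and 456 in shSrsf10. The automatic Scrublet threshold marked 0 barcodes in shCtrl and 223 in shSrsf10, so it had not worked as a common rule. The kept cells held 128971914 shCtrl and 123840029 shSrsf10 UMIs.

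Both libraries were clustered together without integration, after scaling each cell to 10000 UMIs and taking logs. The steps used 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1 with seed 1, and gave 27 clusters. Marker lists were fixed before the data were examined. A cluster took the class with the highest score, the mean log2 level of the class's markers above a low reference. The name was kept with at least 3 markers detected, at 50 CPM and 2-fold over the pooled clusters of other classes. The 10 leading genes also had to not go against it. A first form of the reference left epithelial clusters unnamed under 1 alternative, so the 10th percentile over clusters was taken after that was seen. Tumour, hepatocyte and cholangiocyte markers overlapped and were joined into 1 epithelial class, and Kupffer cells were joined to macrophages, also after the data were seen. Clusters without a name held 127 shCtrl and 35 shSrsf10 cells and were left out of class comparisons. T and NK cells were clustered again with 20 components. The rule that the first subset marker be detected and that no outside class have more leading genes was added after a first naming.

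UMIs were summed per library and class, since cells of 1 library are not replicates, and given as CPM of the class total. A CPM has an exact Poisson interval, a ratio of CPM an exact conditional binomial interval, a share an exact Clopper-Pearson interval and a difference of shares a Newcombe interval, all at 95%. These cover counting error only. A gene with 0 UMIs in 1 library was given as a bound from 3 counts, and so was a share of 0. For 30 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 UMIs, where at least 3 were measured. Its interval came from 1000 Poisson redraws and its percentile from 10000 random lists matched over 20 expression bins. Members at least 1.5-fold higher or lower were counted. Shares of cells with a transcript were taken after thinning each cell to 1000 UMIs, and cells below that were left out. For 40 symbols with several gene IDs, the copy with fewer UMIs was set aside. Coordinates came from GENCODE vM21 on GRCm38.

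Genes were named by a rule fixed before the data were examined. It took Srsf10, Slc2a1, Hk1, Ldha and Myb in the compared classes, and the 8 highest and 8 lowest ratios in each of the 5 classes with the most cells. Not every gene this rule took is printed. Such genes needed at least 50 UMIs over both libraries and 100 CPM in 1 of them. Mitochondrial, ribosomal protein, haemoglobin, receptor segment, sex-linked and unnamed genes were left out. For each list described, 2 to 4 members with the largest ratios were named, and further members, such as Pdcd1, Cd274, Arg1 and Afp, were added after their values were seen because of what they encode. How many cells held each named gene was counted after the values were seen.

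The intervals were tested on simulated data with 20 repeats and 200 changed genes. For 13188 genes at the epithelial depth, 95.2% of intervals held the true ratio at 1.5-fold, and 90.6% of the 1.5-fold and 98.6% of the 2-fold genes had intervals that excluded no difference, as did 7.02% of unchanged genes. For 3085 genes at the macrophage depth these were 95.8%, 55.5%, 83.5% and 4.63%. A planted 2-fold list had a median log2 ratio of 1.00 and 1.01. The simulated counts were Poisson draws, the model that the intervals assume, so coverage near 95% was built in. They had no clumping of UMIs in single cells. The simulation also had no variation between animals, which 1 library per group cannot show.

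Alternatives chosen before the data were examined were a mitochondrial limit of 10%, at least 500 genes per cell, no doublet removal, the automatic doublet threshold, Leiden resolutions 0.5 and 2, separate clustering of the libraries, and shares of immune cells. Others were scaling to a class median of 0, a mean over cells, member limits of 5 and 100 UMIs, a gene limit of 200 UMIs, the mean of members, and thinning to 2000 UMIs or none. Alternatives added later are named where their values are given. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.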

Results

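Single-cell RNA of mouse liver tumours was compared between 1 control library (shCtrl, genotype label WT) and 1 library from tumours carrying a short hairpin RNA against Srsf10 (shSrsf10), a splicing factor. The question named in the series title is how targeting this factor shapes tumour immunity. After filtering, 8767 shCtrl and 7030 shSrsf10 cells remained, with a median of 12371 and 10519.5 UMIs (unique molecular identifiers) per cell. Each group had 1 library, so no difference was checked against replicates and no test between groups was made. A log2 ratio is shSrsf10 over shCtrl in CPM (UMIs of the gene scaled to a common class total), and every interval is at 95% and covers counting error only.

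Srsf10, the target of the hairpin, was lower in the tumour epithelial cells of the shSrsf10 library, at 19.6 CPM against 46.3 CPM in shCtrl, a log2 ratio of -1.24 (-1.31 to -1.17). Over all kept cells its level was 22.2 against 46.5 CPM, a log2 ratio of -1.07 (-1.13 to -0.9998), and -0.53 as a mean over cells of the CPM per cell. In T cells the log2 ratio was -0.36 (-0.72 to 0.01). It was -0.74 (-2.08 to 0.67) in NK cells, -0.15 (-1.09 to 0.73) in macrophages, 0.11 (-1.46 to 1.83) in neutrophils and 0.41 (-0.58 to 1.52) in monocytes, where each interval held 0. With each cell thinned to 1000 UMIs, Srsf10 was seen in 4.21% (3.75 to 4.72) of shCtrl and 1.95% (1.54 to 2.44) of shSrsf10 epithelial cells. In macrophages it was then seen in 13 of 295 shCtrl cells, 4.41%, and 0 of 94 shSrsf10 cells, which on a floor of 3 counts allows up to 3.19% of cells with a UMI and on the exact interval 3.85%, and at 2000 UMIs in 7.43% and 6.45%. The gene (ENSMUSG00000028676) lies on chromosome 4 from 135855747 to 135869908 on the + strand of GRCm38 (mm10). Within the 9 epithelial clusters with at least 50 cells in both libraries, its log2 ratio ran from -1.78 to -0.81, and each interval lay below 0.

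**Figure D1:**
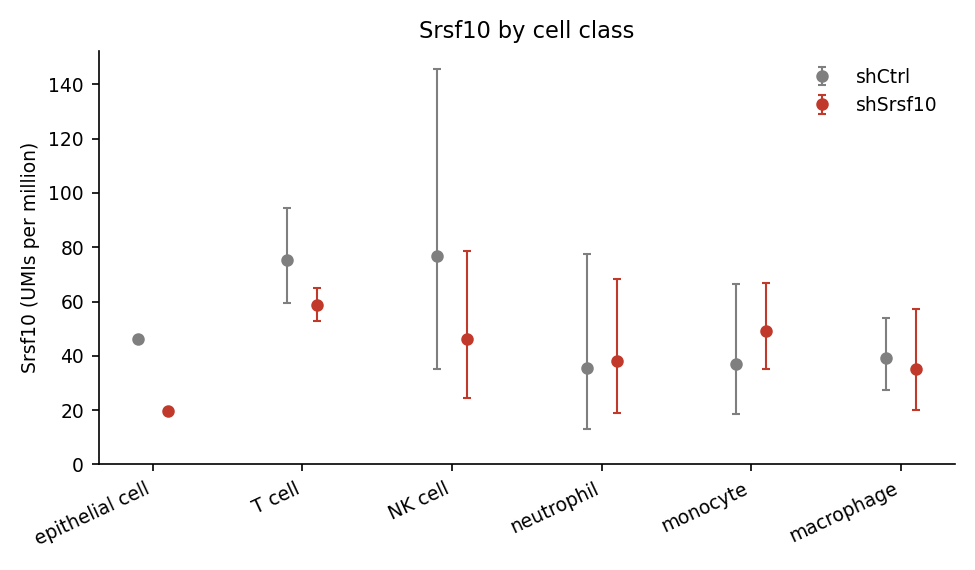
Srsf10 in CPM (vertical axis) by cell class (horizontal axis), with 1 point per library and bars for the exact Poisson 95% interval. The points lie apart in epithelial cells, at 46.3 CPM in shCtrl and 19.6 CPM in shSrsf10, and the intervals overlap in the other classes drawn.

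The shSrsf10 suspension held far more T cells and NK cells, lymphocytes that kill target cells or direct other immune cells, and fewer tumour epithelial cells. T and NK cells together made up 28.2% (27.2 to 29.3) of its kept cells, against 4.75% (4.31 to 5.21) in shCtrl, a fold of 5.95 (5.35 to 6.63). T cells alone were 25.4% against 3.48%, and the cluster named NK cells 2.86% against 1.27%. That cluster scored 4.536 for NK and 4.532 for T cell markers, and only 93 of its 201 shSrsf10 and 31 of its 111 shCtrl cells fell in the NK subset when T and NK cells were clustered again. Epithelial cells were 60.5% (59.4 to 61.7) against 82.9% (82.1 to 83.7), a difference of -22.4 percentage points (-23.8 to -21.0). Macrophages, which engulf debris and present antigen, were lower at 1.76% (1.47 to 2.10) against 4.54% (4.11 to 4.997). Neutrophils, short-lived granulocytes, were 4.78% against 2.27%, a fold of 2.11 (1.76 to 2.52). Monocytes, the blood precursors of many macrophages, were 2.08% against 1.49%. B cells were lower at 0.555% against 1.24%, though not with at least 500 genes per cell (0.198 points), as were mature dendritic cells, the antigen-presenting cells of lymph nodes, at 0.341% against 0.730%. Plasma cells, which secrete antibody, numbered 43 in shSrsf10 and 1 in shCtrl. Other classes with few cells were plasmacytoid dendritic cells (20 in shCtrl and 18 in shSrsf10), mast cells or basophils (9 and 16) and fibroblasts (23 and 11).

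Of immune cells alone, T and NK cells were 72.7% in shSrsf10 and 30.9% in shCtrl, and macrophages were 4.54% against 29.5%. Neutrophils and monocytes stood lower in shSrsf10 on this scale, at 12.3% against 14.8% and 5.35% against 9.73%. The macrophage class joined a cluster of 321 shCtrl and 122 shSrsf10 cells with a cluster of 77 shCtrl and 2 shSrsf10 cells led by Cd5l, Clec4f and Fcna, genes of Kupffer cells, the resident macrophages of the liver. Shares can follow the cell sort and the spin that the labels describe, and each group was 1 suspension.

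**Figure D2:**
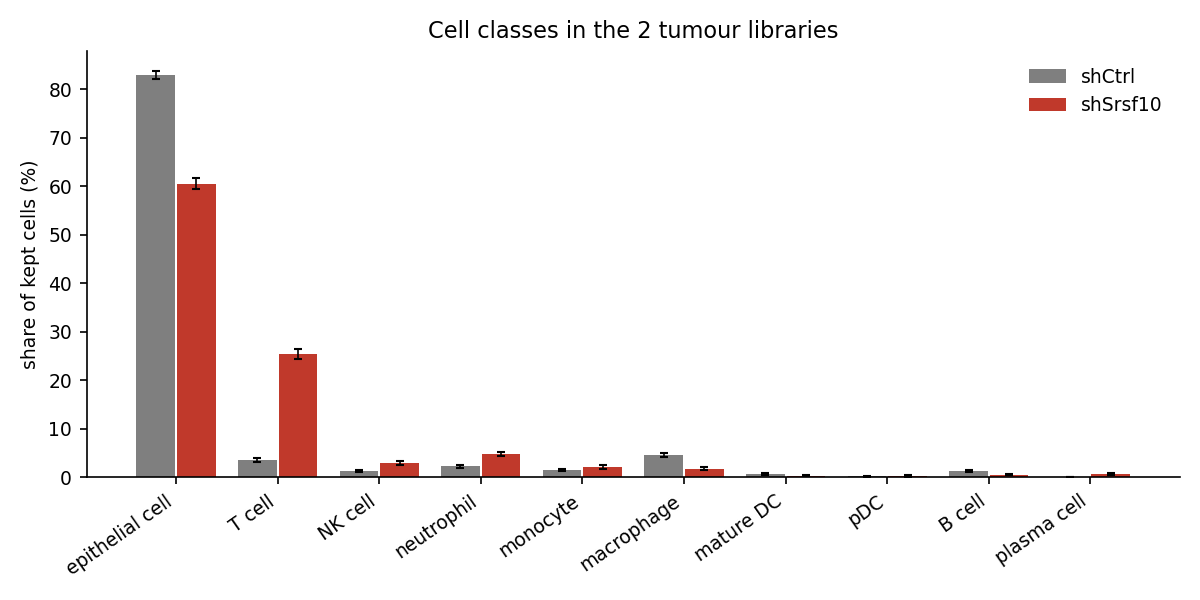
Share of kept cells in percent (vertical axis) for 10 cell classes (horizontal axis), with 1 bar per library and exact Clopper-Pearson 95% intervals. T cells stand at 3.48% in shCtrl and 25.4% in shSrsf10, and macrophages at 4.54% and 1.76%.

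Among the T and NK cells, CD8 T cells, the subset that kills cells presenting foreign peptide, were 51.1% (48.8 to 53.3) in shSrsf10 and 20.9% (17.1 to 25.1) in shCtrl. The shCtrl share depends on the clustering, since the shares were 49.8% and 3.61% at subset resolution 0.5 and 50.6% and 28.6% at 2. CD4 T cells other than regulatory ones were 16.1% against 5.05%. Regulatory T cells, which restrain other T cells, were 1.46% (0.981 to 2.09) against 8.41% (5.93 to 11.5). Of all kept cells, a share taken after the results were seen, they were 0.413% (0.276 to 0.592) in shSrsf10 and 0.399% (0.278 to 0.555) in shCtrl, from 29 and 35 cells, so the lower share among T and NK cells goes with the larger number of other T cells. CD8 T cells were 14.4% and 0.992% of all kept cells. The NK subset, smaller than the NK class, was 4.79% (95 cells) against 7.45% (31 cells). Of all kept cells the NK subset was higher in shSrsf10, at 1.35% against 0.354%. Subset clusters without a name held 26.6% of the shSrsf10 and 58.2% of the shCtrl cells. These shares rest on 1984 shSrsf10 and 416 shCtrl cells. A naming rule added after a first naming set most of the unnamed clusters aside, and without it regulatory T cells were 8.92% against 28.8%, a naive T cell subset was 6.70% against 24.0%, and CD8 T cells were the same. The cluster of the naive subset was led by Apoe, Trf, Alb, Afp and Ttr, which are liver and tumour genes.

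T cells of the shSrsf10 library carried more RNA of killing, and genes of regulatory cells made up less of their RNA. The chemokine Ccl5 stood at 12465 against 3198 CPM, a log2 ratio of 1.96 (1.91 to 2.01), and the granule protease Gzmk at 215 against 38.2 CPM, 2.49 (2.03 to 2.99). Cytotoxic effector genes had a median log2 ratio of 0.53 (0.41 to 1.00), but of -0.02 within the T cell cluster that both libraries filled. Over the whole class, 7 of 15 members were at least 1.5-fold higher, none lower and 8 between. Gzmb was at 1.40 and Ifng, the gene of interferon gamma, at 1.19. Regulatory T cell genes had a median of -1.03 (-1.25 to -0.68), with 1 of 10 higher, 8 lower and 1 between, in a class where 1008 of 1783 shSrsf10 and 80 of 305 shCtrl cells were CD8 T cells. Within the regulatory T cell subset itself, of 29 shSrsf10 and 35 shCtrl cells, the same list was at 0.78 (0.59 to 1.01), with 7 of 9 higher and none lower. Over the whole T cell class, the transcription factors Ikzf2 and Foxp3 of regulatory T cells were at -2.54 and -1.89, the suppressive cytokine Il10 was at -1.65, and the costimulatory receptor Icos was at 0.59. Genes induced by type I interferon, the antiviral cytokines, had a median of 1.34 (0.58 to 1.49), with 8 of 13 higher, 1 lower and 4 between, led by Ifit3 at 2.82 and Irf7 at 2.23.

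T cell exhaustion genes, which mark long antigen exposure, had a median of -0.47 (-0.76 to -0.34) in T cells, with 1 of 14 higher, 5 lower and 8 between. Under the automatic doublet threshold this median was -0.070 and that of the cytotoxic genes 1.02. The exhaustion factor Tox was at -1.92, the costimulatory receptor Tnfrsf9 at -1.51, and the inhibitory receptor Pdcd1 at -0.54. Naive and memory genes had a median of 0.49 (0.16 to 0.76), with 5 of 10 higher, 2 lower and 3 between. The factor Lef1 was at 2.35, and Ccr7, a homing receptor, was at -1.64. Within the T cell cluster that both libraries filled, the exhaustion median was 0.0031 and the naive and memory median -0.39. After thinning to 1000 UMIs, Gzmb was seen in 52.5% (50.1 to 54.9) of shSrsf10 and 26.8% (21.5 to 32.6) of shCtrl T cells, against 0.26% and 0.04% of epithelial cells. Pdcd1 was seen in 10.8% against 24.1% of T cells and in no epithelial cell, and Foxp3 in 0.53% against 2.30% of T cells. Among cells with at least 1000 UMIs, the median depth before thinning was 2576.5 and 2431 UMIs in T cells and 25946 and 16301 UMIs in epithelial cells of shSrsf10 and shCtrl.

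Other T cell genes with large ratios were Epsti1, an interferon-induced gene, at 2.41, the protease inhibitor Ctla2a at 2.08, the migration receptor S1pr4 at 1.92 and Gramd3 at 1.81. Ly6c2 (4.06) and Plac8 (1.81) were also higher, and both are on the list of monocyte markers. They were held by 1086 and 1285 of the 1783 shSrsf10 T cells. Ly6c2 was also among the leading genes of CD8 clusters with 750 and 205 shSrsf10 cells. Lower were the cytokine Il4 at -2.91, the transcription factor subunit Taf10 at -2.70, the protease inhibitor Stfa3 at -2.67, the integrin Itgav at -2.64, the chemokine Xcl1 at -2.59 (155 against 934 CPM), the cytokine Tnfsf8 at -2.39, and Ttr at -2.44, a marker of the epithelial cells. A single shCtrl cell gave 72.0% of the shCtrl UMIs of Stfa3, and Il4 was held by 10 shCtrl and 8 shSrsf10 cells. The class joined 3 clusters, of which the Gzmb cluster held 941 shSrsf10 and 18 shCtrl cells. In the cluster that both libraries filled, with 249 shCtrl and 378 shSrsf10 cells, the medians were -0.02 for cytotoxic, 0.00 for exhaustion and -0.39 for naive and memory genes, so the class medians of these lists did not hold within it.

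The CD8 T cells of the libraries came from different clusters. In shSrsf10, 750 and 205 of the 1013 cells lay in a pair of clusters led by genes such as Gzma, Cd8b1 and Gzmb, which held 9 and 6 shCtrl cells. In shCtrl, 72 of the 87 cells lay in a cluster led by the same genes and by Tcrg-C2 and the killer cell receptors Klrd1 and Klre1, which held 58 shSrsf10 cells. Over the whole subset, the exhaustion median was -1.25 (-1.50 to -0.85), with 2 of 12 higher, 8 lower and 2 between. Rgs16, a brake on receptor signalling, was at -2.60, Tox at -2.19, Tnfrsf9 at -2.06, Pdcd1 at -1.54 (-1.85 to -1.21) and the inhibitory receptor Lag3 at -1.10. The naive and memory median was 1.54 (1.01 to 1.83), with 7 of 9 higher, none lower and 2 between. Lef1 was at 2.40, S1pr1, which guides exit from tissue, at 2.08 and Satb1 at 1.54. The memory factor Tcf7 had 91 UMIs in shSrsf10 and 1 in shCtrl, a log2 ratio of 2.91 (0.40 to 8.23). Cytotoxic effector genes had a median of 0.12 (-0.01 to 0.71), with 7 of 15 higher, 1 lower and 7 between. Ifng was at 2.04, Gzmk at 1.91 and Gzma, another granule protease, at -0.79. Genes induced by type I interferon had a median of 1.14 and those induced by interferon gamma 1.03. After thinning, Pdcd1 was seen in 8.44% of shSrsf10 and 34.7% of shCtrl CD8 T cells. Within the cluster of 72 shCtrl and 58 shSrsf10 cells, the exhaustion median was 0.062 (-0.16 to 0.33), with 8 of 10 genes between, the cytotoxic median 0.31 and the naive and memory list was not measurable, so the lower exhaustion median was not seen there. In the same cluster the type I interferon median was 0.29 (-0.20 to 0.64), with none of 4 genes at least 1.5-fold higher. The interferon gamma median there was 0.51 (-0.04 to 1.02), with 2 of 4 higher. At subset resolution 0.5 the naive and memory, type I interferon and interferon gamma medians turned to -0.59, -0.10 and -0.48.

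Tumour epithelial cells of the shSrsf10 library had far more RNA for MHC class II, which presents peptide to CD4 T cells, and for genes induced by interferon gamma. H2-Aa, an MHC class II chain (chromosome 17, 34282744 to 34287823, - strand), stood at 169 against 13.8 CPM, a log2 ratio of 3.61 (3.54 to 3.68). Cd74, the chaperone of MHC class II (chromosome 18, 60803848 to 60812652, + strand), was at 839 against 89.7 CPM, 3.23 (3.20 to 3.25). All 9 measured MHC class II genes were at least 1.5-fold higher, with a median of 3.19 (3.14 to 3.22), from Ctss, a protease that trims Cd74, at 0.86 to H2-DMb2, a peptide-loading chain, at 4.69. All 15 measured genes induced by interferon gamma were at least 1.5-fold higher, with a median of 2.51 (2.26 to 2.67). They included the guanylate-binding proteins Gbp2 (3.12) and Gbp5 (3.05), the T cell-attracting chemokine Cxcl9 (2.89), the checkpoint ligand Cd274 (2.67), the transcription factor Irf1 (1.97), and the feedback inhibitor Socs1 (0.92).

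MHC class I genes, which present peptide to CD8 T cells, had a median of 1.12 (1.10 to 1.13) in epithelial cells, with 14 of 17 higher, none lower and 3 between. Psmb9 (2.27) and Psmb8 (2.01), subunits of the immunoproteasome, and the peptide transporter genes Tap2 (2.18) and Tap1 (1.94) led, H2-D1 was at 1.47, B2m at 1.12 and the chaperone Calr at -0.18. H2-K1, an MHC class I chain and 1 of the 14, had only 2.36 CPM in shCtrl and 6.59 CPM in shSrsf10 epithelial cells. T cells had 2330 and 3097 CPM of it. Immune RNA was estimated at 0.175% of the epithelial UMIs in shCtrl and 0.278% in shSrsf10. At these shares, RNA at the T cell levels would reach the epithelial levels of H2-K1 in both libraries. Its rise is therefore no evidence of more H2-K1 RNA made by the tumour cells, and no test of this gene was run. Genes induced by type I interferon had a median of 0.85 (0.59 to 0.96), with 8 of 15 higher, 1 lower and 6 between, from Oasl2 at 1.85 and Zbp1 at 1.83 to Ifit1 at -1.01. Among chemokines, which draw leukocytes, 9 of 18 were higher, 3 lower and 6 between, with a median of 0.65 (0.58 to 0.84). The monocyte attractant Ccl2 was at 3.37, Ccl5 at 3.18 and Cxcl10 at 2.12 (352 against 80.8 CPM). Ccl5 is also a gene of T cells, which had 12465 CPM of it in shSrsf10 and 3198 CPM in shCtrl. Whether immune RNA gave the rise of Ccl5 in epithelial cells was not tested. Ly6a, a surface protein of progenitors and activated lymphocytes, was at 3.16. Cytotoxic genes of T cells also carried more UMIs in epithelial cells, with a median of 3.18 over 11 members, which are genes of another cell type. Within the 9 single clusters, the median of the MHC class II and interferon gamma members lay between 0.46 and 2.89, and in the lowest cluster 21 of 23 members lay above 0. That cluster held 1813 of the 4254 shSrsf10 and 180 of the 7270 shCtrl epithelial cells, while the clusters with most shCtrl cells held 1679 and 1604 of them and 369 and 203 shSrsf10 cells.

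**Figure D3:**
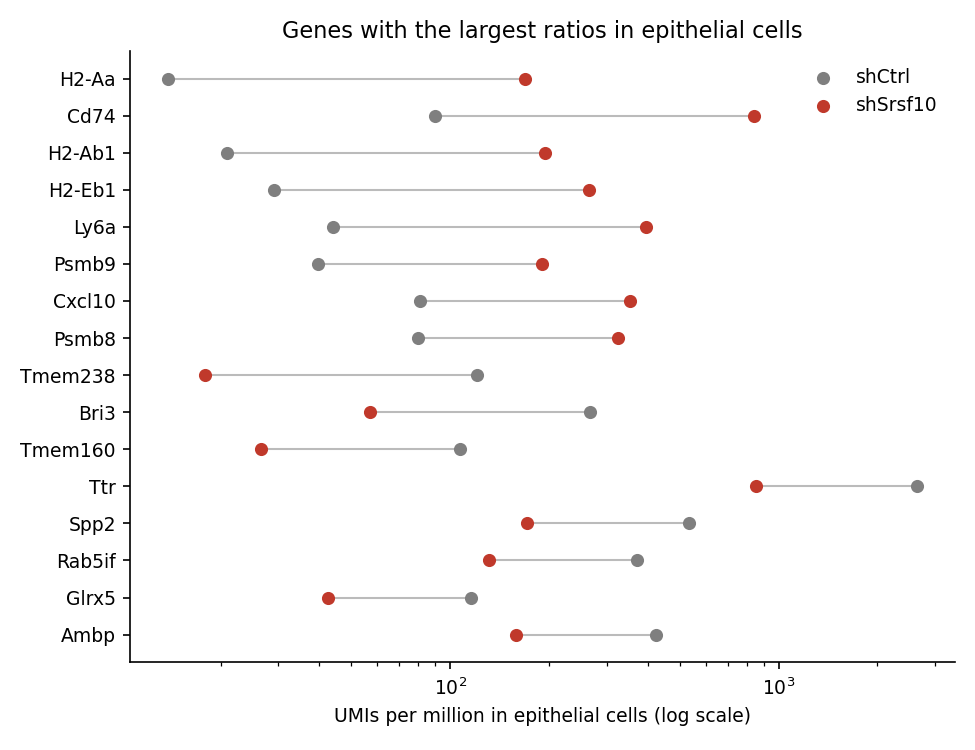
Level in epithelial cells in CPM (horizontal axis, log scale) of the 16 genes with the highest and lowest ratios, with 1 point per library joined by a line. H2-Aa goes from 13.8 to 169 CPM and Ttr from 2643 to 851 CPM between shCtrl and shSrsf10.

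**Figure D4:**
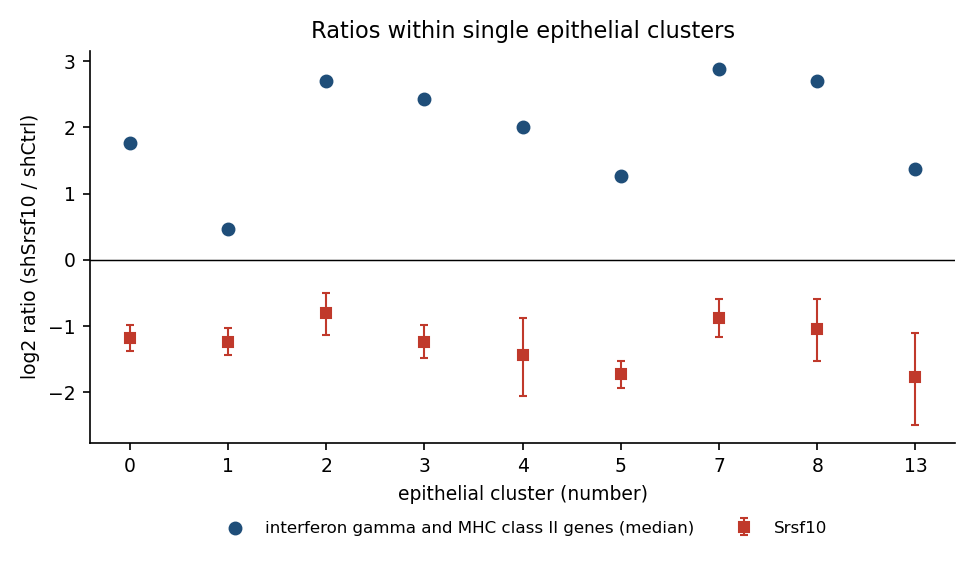
Log2 ratio (vertical axis) within each of 9 epithelial clusters (horizontal axis, cluster number), for Srsf10 with its 95% interval and for the median of the interferon gamma and MHC class II genes, drawn without an interval. The medians run from 0.46 to 2.89 and the Srsf10 ratios from -1.78 to -0.81.

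Genes of secreted liver proteins were lower in the shSrsf10 epithelial cells. Their median was -0.80 (-0.87 to -0.71), with 1 of 17 higher, 9 lower and 7 between. Apoc3, an apolipoprotein, was at -1.87, the protease inhibitor Serpina1a at -1.73, and the thyroid hormone carrier Ttr (chromosome 18, 20665280 to 20674321, + strand) at -1.64 (851 against 2643 CPM), while the haemoglobin scavenger Hp was at 0.99. Other lower genes were Tmem238 (chromosome 7, 4784557 to 4789656, - strand) at -2.75 (-2.82 to -2.68), with 18.0 against 121 CPM, Bri3 (chromosome 5, 144244437 to 144446757, + strand) at -2.23 (-2.27 to -2.19), Tmem160 at -2.01, the secreted phosphoprotein Spp2 at -1.63, Rab5if at -1.50, the iron-sulfur protein Glrx5 at -1.45 and Ambp, a secreted plasma protein, at -1.42. Fetal liver and hepatoma genes had a median of -0.27, with 1 of 13 higher, 1 lower and 11 between. The growth factor Igf2 was at -2.45, the fetal serum protein Afp at -0.53, and the cell surface proteoglycan Gpc3 at 0.38.

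Genes of glycolysis, the breakdown of glucose, differed little between the epithelial cells, with a median of 0.17 (0.16 to 0.20) and 2 of 17 higher, 2 lower and 13 between. The lactate exporter Slc16a3 was at 1.66, Eno1 at 0.59, Hk2, a hexokinase, at -0.67, and the glycolysis activator Pfkfb3 at -1.48. The glucose transporter Slc2a1 was at -0.02 (-0.06 to 0.02), the lactate dehydrogenase Ldha at 0.25 (0.24 to 0.26) and the hexokinase Hk1 at -0.34 (-0.44 to -0.25). The transcription factor Myb had 2 UMIs in shCtrl and 3 in shSrsf10 epithelial cells. In T cells Slc2a1 was at 1.39 (0.69 to 2.19) and in neutrophils at 1.10 (0.31 to 1.97), and Ldha was at 0.92 (0.64 to 1.20) in monocytes and 0.41 (0.23 to 0.58) in macrophages. Hypoxia genes in epithelial cells had a median of -0.06 (-0.10 to -0.03), with 12 of 13 between and the vessel growth factor Vegfa at -0.78. This sign turned to 0.02 when the class median was set to 0. Cell cycle genes had a median of 0.18 (0.15 to 0.20), and all 24 lay between. The SR protein genes, splicing factors related to Srsf10, had a median of -0.38 (-0.41 to -0.31), with 2 of 14 lower and 12 between, and Srsf9 was at -0.97, Srsf2 at -0.70 and Srsf1 at -0.56. Stress genes had a median of 0.02 and a mean of -0.16. The median over all 13188 genes measured in this class was -0.08.

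**Figure D5:**
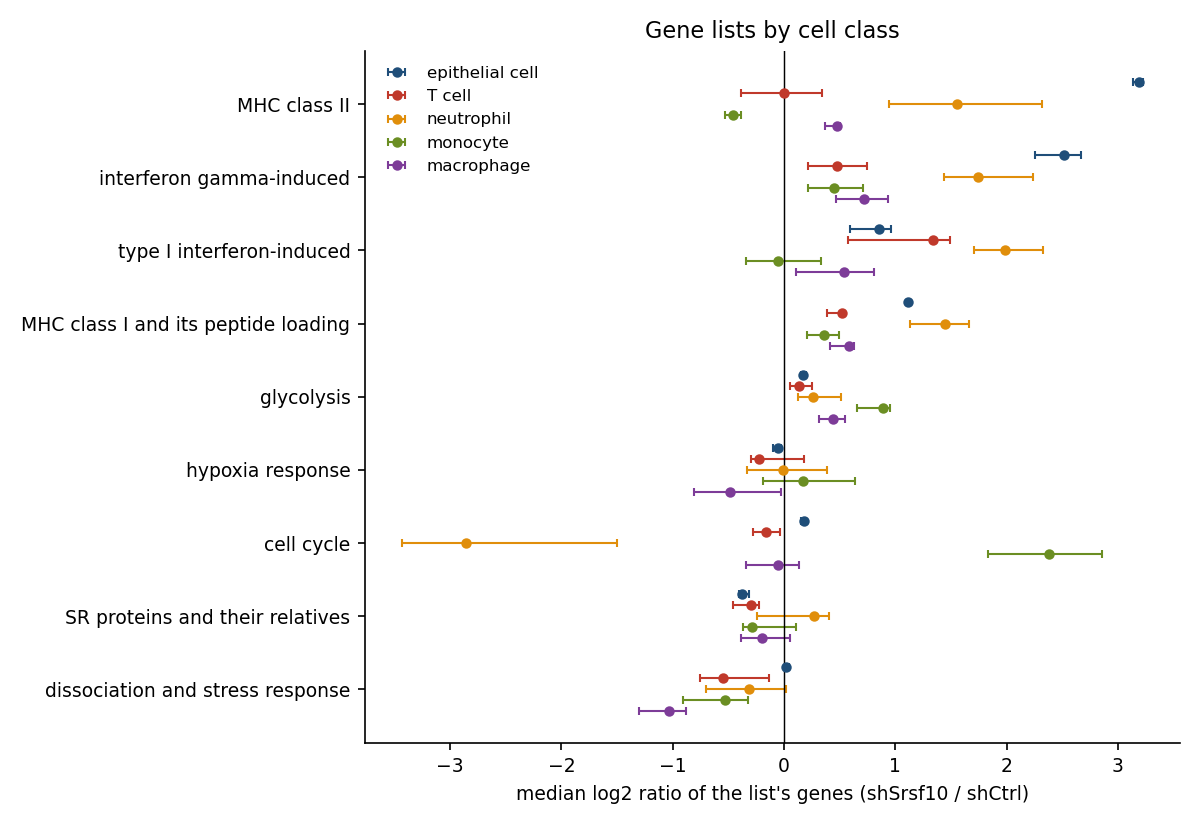
Median log2 ratio of 9 gene lists (horizontal axis) in 5 cell classes (colours), with bars for the interval from Poisson redraws of the counts. MHC class II lies at 3.19 in epithelial cells and at -0.45 in monocytes, and the cell cycle at 2.38 in monocytes and -2.86 in neutrophils.

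Neutrophils of the shSrsf10 library had more RNA of interferon-induced genes. Type I interferon genes had a median of 1.99 (1.71 to 2.33), and all 10 measured were at least 1.5-fold higher, with Irf7, a regulator of interferon genes, at 2.45. Rtp4, which is not on that list, was at 2.70. All 8 measured interferon gamma genes were higher, with a median of 1.75 (1.44 to 2.23) and Gbp2 at 904 against 136 CPM, 2.73 (2.11 to 3.41). Gbp7 was at 4.30 (2.39 to 7.37) from 67 against 2 UMIs, the antibody receptor Fcgr4 at 3.75, the neutrophil attractant Cxcl1 at 2.79, the sulfotransferase Tpst2 at 2.50 and Cxcl10 at 2.36. MHC class I genes had a median of 1.45 (1.13 to 1.66), with 13 of 16 higher, 2 lower and 1 between. The median over all 1153 measured genes in this class was 0.23. Tumour-associated neutrophil genes had a median of 0.10 (-0.13 to 0.46), with 6 of 13 higher, 4 lower and 3 between. The prostaglandin enzyme Ptgs2 and the chemokine Cxcl2 were both at 1.07, Cd274 was at 0.86 and Ccl4 at -0.91.

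Neutrophil granule genes, made as these cells mature, had a median of -0.87 (-1.04 to -0.57), with 1 of 11 higher, 6 lower and 4 between. The antimicrobial peptide Camp was at -2.19, Ngp at -1.83 and Ltf, lactoferrin, at -1.30. The Camp UMIs came from 3 shCtrl and 2 shSrsf10 cells, and without these cells the granule median was -0.20. It turned to 1.02 with at least 500 genes per cell and to 0.84 under the automatic doublet threshold. Cell cycle genes had a median of -2.86 with 4 of 5 lower, and -1.41 without those cells. Chil3 was at -3.67, is a monocyte marker and came from 3 shCtrl and 2 shSrsf10 cells. Ccl5 at -3.22 came from 4 and 12 cells, the heat shock gene Hspa1a was at -3.03, Bri3 at -2.22, the tubulin Tubb5 at -2.16 and the histone chaperone Anp32b at -2.11, and Ttr at -2.49 is a marker of epithelial cells. SR protein genes were at a median of 0.27 and stress genes at -0.32. Cells carried a median of 789.5 UMIs in shSrsf10 and 681 in shCtrl.

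Monocytes of the shSrsf10 library included cells with granule protease RNA of early myeloid cells. Elane, neutrophil elastase (chromosome 10, 79886247 to 79888215, + strand), had 2081 UMIs in 22 of 146 shSrsf10 cells, 15.1% (9.69 to 21.9), and none in 131 shCtrl cells, at least 247-fold higher against a floor of 3 counts. Mpo, myeloperoxidase, was at least 143-fold, the protease Ctsg at least 102-fold and the myeloid progenitor gene Ms4a3 at least 22.9-fold higher on the same floor. The monocyte name of these cells depends on the clustering. At Leiden resolutions 0.5 and 2, and with at least 500 genes per cell, a cluster with Elane and Mpo among its leading genes stayed unnamed. With each cell thinned to 1000 UMIs, Elane was seen in 12.7% (7.69 to 19.3) of shSrsf10 monocytes and in 0 of 115 shCtrl monocytes, which on the floor of 3 counts allows up to 2.61% of cells with a UMI, and in no T or epithelial cell of either library. Prtn3, a related protease, was at 8.54 (6.69 to 11.6), seen after thinning in 20.4% against 0.870% of monocytes and 1.75% against 1.64% of epithelial cells, the mitosis gene Birc5 at 4.47, Ctla2a at 4.34 and the killer cell gene Nkg7 at 4.19. All 21 measured cell cycle genes were at least 1.5-fold higher, with a median of 2.38 (1.83 to 2.85). Glycolysis genes had a median of 0.89 (0.65 to 0.95), with 9 of 14 higher, 2 lower and 3 between. Without the cells holding Elane, Mpo, Ctsg or Camp, the cell cycle median was 1.68 and that of glycolysis 0.57. The counts of cells with granule genes were made after the values were seen.

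Complement and lipid-handling genes of macrophages were lower in these monocytes, with a median of -0.64 (-0.74 to -0.39), 8 of 14 lower and 6 between, and the lipid carrier Apoe at -2.02. This median turned to 0.026 at Leiden resolution 2 and to 0.10 with each library clustered on its own. The alternative (M2-type) genes had a median of -0.52 (-0.98 to 0.03), with 3 of 8 higher, 4 lower and 1 between, the classical (M1-type) genes -0.01, genes induced by interferon gamma 0.45 (0.21 to 0.71) and those induced by type I interferon -0.06. MHC class II genes had a median of -0.45 (-0.53 to -0.38), which turned to 0.26 without the cells holding granule genes, 0.24 as a mean over cells, 0.15 with no doublets removed, 0.40 at Leiden resolution 2 and 0.49 with separate clustering. The chemokine Ccl24 was at -2.73, Metrnl at -2.79, Bri3 at -3.13, and the epithelial markers Ttr at -3.47 and Afp at -3.02. Ngp was at -9.77 and Camp at least as low as -8.29 on the floor of 3 counts, but 1 shCtrl cell held all 334 Camp UMIs and 1 held all 311 shCtrl Ngp UMIs. SR protein genes were at a median of -0.28 and stress genes at -0.53.

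Macrophages of the shSrsf10 library had less RNA of Kupffer cell and stress genes and more of interferon-induced genes. Folr2, a folate receptor of resident macrophages, was at -4.16 (-6.46 to -2.58), and Fcna (-3.09), Clec4f (-3.05) and Cd5l (-2.59) were lower with the smaller Kupffer-type cluster. The transcription factor Id3 was at -4.03, the apolipoprotein Apoc1 at -2.74, and the heat shock genes Hspa1b and Hspa1a at -5.22 and -3.35 (83.7 against 851 CPM). Stress genes had a median of -1.03 (-1.31 to -0.88), with 15 of 17 lower and 2 between. M2-type genes had a median of -0.19 (-0.80 to -0.02), with 1 of 13 higher, 5 lower and 7 between, including the lectins Mgl2 at -1.51 and Mrc1 at -0.998, while Arg1, arginase, was at -0.01. This median turned to 0.22 under the automatic doublet threshold. M1-type genes had a median of 0.39 (0.20 to 0.53), with 5 of 12 higher, 1 lower and 6 between. Ccl5 was at 2.72 (923 against 140 CPM), with 48.1% of its shCtrl UMIs in 1 cell, and Cxcl9 was at 1.24. Cytotoxic genes, which are genes of T and NK cells, were at a median of 1.95 (1.43 to 2.57) in macrophages, with 4 of 5 higher. After thinning, Mrc1 was seen in 4.26% of shSrsf10 and 9.83% of shCtrl macrophages and Arg1 in 3.19% and 6.44%, with overlapping intervals.

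Macrophage genes induced by interferon gamma had a median of 0.72 (0.46 to 0.93), with 8 of 13 higher and 5 between. Those of type I interferon were at 0.54, MHC class I genes at 0.58 (0.41 to 0.63) and MHC class II genes at 0.48 (0.37 to 0.50), where 1 of 9 was higher and 8 lay between. Ly6a was at 1.99, Gbp2b at 1.68, the signalling adaptor Scimp at 1.58, the protease inhibitor Serpina3g at 1.48, the chemokine Ccl8 at 1.43, Ms4a4b, a T cell gene, at 3.81 from 47 against 7 UMIs, and H2-M2 at 2.06, with 46.6% of its shSrsf10 UMIs in 1 cell. Complement and lipid-handling genes had a median of -0.28 (-0.40 to -0.22), with 1 of 15 higher, 7 lower and 7 between. Spp1, osteopontin, was at -2.31 and the lipid receptor Trem2 at -1.63, and the median turned to 0.0895 under the automatic doublet threshold. Chemokines had a median of -0.76 (-0.93 to -0.29), with Ccl2 at -1.26 and Cxcl2 at -1.17, and 0.36 over members with at least 100 UMIs. Glycolysis genes had a median of 0.44 (0.31 to 0.55), hypoxia genes -0.48 (-0.81 to -0.02), SR protein genes -0.20 and cell cycle genes -0.05.

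In the class named NK cells, of which many fell in no NK subset, cytotoxic genes were at 0.21 (0.12 to 0.63), with 6 of 13 higher, 1 lower and 6 between, exhaustion genes at -0.03 and naive and memory genes at 0.24. The regulatory genes were at 0.54 and the cell cycle genes at -0.39, each from 3 measured members, while SR protein genes were at 0.21 and stress genes at -0.08. In the NK subset of 95 shSrsf10 and 31 shCtrl cells, cytotoxic genes were at 0.47 (0.25 to 0.70). Exhaustion genes there were at -0.58 (-1.26 to 0.15) from 3 measured members. SR protein genes were at -0.22 (-0.71 to 0.33) and stress genes at -0.36 (-0.83 to 0.39) in that subset. In T cells, SR protein genes had a median of -0.30, cell cycle genes -0.17 and stress genes -0.55. Genes of secreted liver proteins had medians of -2.41 in T cells, -2.12 in NK cells, -1.12 in neutrophils, -2.56 in monocytes and -1.69 in macrophages.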

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

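Apart from the comparisons of receptor segments and of the mitochondrial limit, the tests below were chosen after the results were seen.

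Cell cycle genes stood apart between myeloid classes, at a median log2 ratio of 2.38 in monocytes and -2.86 in neutrophils, a difference of 5.24. MYC and ribosome biogenesis genes, which mark growing cells, were at 0.85 in monocytes and -1.64 in neutrophils, a difference of 2.49. The neutrophil value rests on 4 genes and was 0.048 with no doublets removed, and the monocyte value was -0.33 at Leiden resolution 2 and -0.26 with separate clustering. The neutrophil cell cycle value rests on 5 genes. Over the alternatives, the cell cycle median ran from 0.49 to 2.89 in monocytes and from -3.41 to -0.29 in neutrophils. Chemokines were at 0.65 in epithelial cells and -0.76 in macrophages, a difference of 1.41, but the macrophage value was 0.36 over members with at least 100 UMIs. Each was picked out because the class medians lay at least 1.5-fold in opposite directions, with intervals on either side of 0. None of these differences was tested.

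T and NK cells were 5.95-fold more frequent in the shSrsf10 library. A lower capture of tumour epithelial cells alone would raise every other class alike, but the macrophage share was 0.389 of its shCtrl value. A loss of shallow cells below 500 UMIs in shCtrl would raise neutrophils, which have fewer UMIs per cell than T cells, at least as much, and their fold was 2.11. Different handling or sorting of the tumours stays open, since each group was 1 suspension. The loss of Srsf10 in the tumour cells may also lie behind the difference, and it cannot be told apart from handling in this design.

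MHC class II and interferon gamma genes were higher in the shSrsf10 epithelial cells. Immune RNA in these cells, estimated from genes of immune cells at 0.175% of UMIs in shCtrl and 0.278% in shSrsf10, gave 0.0305% of the difference for the median of 23 members, which argues against it as the whole cause. A different mix of tumour clusters was tested within 9 clusters, where the lowest median was 0.46 and missed the bound of 0.5 set for excluding it, so a part played by the mix stays open. The T cells of the same library had more Ifng RNA, and interferon gamma from these cells is a candidate explanation that was not tested.

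Of 865 genes measured in all 5 main classes, 12 were at least 2-fold lower in every class of the shSrsf10 library and none was higher in every class. They were Bri3, Camk1d, Cdk8, Peak1, Scand1, Ttr and the mitochondrial genes mt-Atp6, mt-Co1, mt-Co2, mt-Nd1, mt-Nd2 and mt-Nd4. Free tumour RNA as the only source would leave lower levels in the other classes than in epithelial cells. That held for 8.33% of the genes, Ttr alone. Free RNA added to a class's own RNA was not tested, so it stays open for the other genes too. Genes of secreted liver proteins were also lower in each immune class compared. Different kits would part the receptor V and C segments by over 5-fold. The beta chain ratio differed by 1.25 (0.672 to 2.57), an interval that passes the bound of 2 set for excluding kits, and the alpha chain ratio by 2.18 (1.03 to 5.52), so kits stay open. A 10% mitochondrial limit, meant to take out damaged cells, moved the median of the genes outside the mitochondrial genome by -0.037, but it took out only 3.06% of the shCtrl cells and says little. More damage in shCtrl stays open, since 6 of the 12 genes were mitochondrial and 3.78% of shCtrl against 0.847% of shSrsf10 barcodes exceeded 20% mitochondrial UMIs. Loss of Srsf10 in each cell stays open, since its log2 ratio was 0 or above in 2 classes but with wide intervals.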

How the results depend on the processing

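The alternatives that took T cell cluster 9 alone, epithelial cells without low-UMI clusters, cluster 12 of the macrophages, monocytes or neutrophils without cells holding granule genes, CD8 subset cluster 7 alone, the NK subset in place of the NK class, subsets without the added rule and subset shares of all kept cells were chosen after the results were seen. No paired analysis was possible because each group had 1 library. Over the 13 main answers, 125 of 129 alternative values kept their sign. Of the 129, 94 stayed within the range set for the reported value, 31 moved beyond it and 4 reversed. Over the other 87 results, 762 of 831 kept their sign, 631 stayed within, 173 moved and 27 reversed. That range was the counting interval, except for counts of largest-ratio genes shared with the reported list. Such counts have no counting interval and cannot change sign. They gave 10 of the 129 values, in epithelial cells, all within the range at 14 to 16 genes. Of the 831, they gave 10 each in T cells, neutrophils and macrophages and 8 in monocytes. The cause was not tested for the changes below, except where the choice of cells or denominator sets it.

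As shares of immune cells, T and NK cells differed by 41.8 points and macrophages by -25.0, and monocytes (-4.38) and neutrophils (-2.47) reversed. Scaled to a median of 0, Srsf10 in epithelial cells was at -1.16, glycolysis 0.25, MHC class I 1.20 and hypoxia 0.024. As a mean over cells, Srsf10 was at -1.13, glycolysis 0.23, MHC class I 1.27 and MHC class II in monocytes 0.24. As a mean of members, glycolysis was at 0.11, MHC class I 1.16, M2-type genes in macrophages -0.86 and stress in epithelial cells -0.16. With at least 100 UMIs per member, chemokines in macrophages were at 0.36. Without low-UMI clusters, epithelial glycolysis was at 0.14. In T cell cluster 9 alone, cytotoxic genes were at -0.017, exhaustion 0.0031, naive and memory -0.39 and cell cycle 0.037. Without cells holding Elane, Mpo, Ctsg or Camp, MHC class II in monocytes was at 0.26.

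With at least 500 genes per cell, T and NK cells differed by 25.2 points and B cells by 0.198, and neutrophil granule genes were at 1.02. With no doublets removed, epithelial cells differed by -17.1 points, epithelial glycolysis was at 0.14 and interferon gamma genes 2.71, M2-type genes -0.007, MHC class II in monocytes 0.15 and MYC genes in neutrophils 0.048. With the automatic doublet threshold, macrophages differed by -3.45 and epithelial cells by -15.2 points, epithelial glycolysis was at 0.14 and interferon gamma genes 2.72, M2-type genes 0.22, macrophage complement and lipid genes 0.0895, T cell cytotoxic genes 1.02, exhaustion -0.070 and neutrophil granule genes 0.84. At Leiden resolution 2, epithelial cells differed by -17.9 points, and complement and lipid genes (0.026), MHC class II (0.40) and MYC genes (-0.33) reversed in monocytes. With separate clustering, T and NK cells differed by 27.8 and epithelial cells by -17.3 points, epithelial glycolysis was at 0.15, and complement and lipid genes (0.10), MHC class II (0.49) and MYC genes (-0.26) reversed in monocytes. The CD8 difference was 46.2 points at subset resolution 0.5, where naive and memory (-0.59), type I interferon (-0.10) and interferon gamma genes (-0.48) reversed, and 21.9 at resolution 2. In CD8 cluster 7 alone, exhaustion was at 0.062. Without the added rule, regulatory T cells differed by -19.9 points. As shares of all kept cells, CD8 T cells differed by 13.4 points, and regulatory T cells (0.0133), the NK subset (0.998) and unnamed cells (4.75) reversed, the first with an interval that holds 0.

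No value was had for NK lists with at most 10% mitochondrial UMIs, at least 500 genes, resolution 2 or separate clustering, nor for monocytes with at least 500 genes or resolution 0.5, naive, regulatory and cell cycle genes in the NK subset, and naive and memory genes in CD8 cluster 7. Among the 6 compared classes, depth limits neutrophils and NK cells most, with medians of 681 and 789.5 UMIs per neutrophil and 999 and 1244 UMIs per NK cell in shCtrl and shSrsf10.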

Other observations

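The genes of sex and the MHC class I gene below were chosen after their values were seen. The tumour epithelial cells and the T cells differed in the levels of these genes. Xist, the RNA of the inactive X chromosome, was at 695 CPM in shCtrl and 635 CPM in shSrsf10 epithelial cells, while the Y-linked gene Ddx3y was at 0.0637 and 0.0787 CPM. T cells had Ddx3y at 37.2 and 36.2 CPM and Xist at 46.3 and 8.62 CPM. H2-K1, an MHC class I chain, was at 2.36 and 6.59 CPM in epithelial cells against 2330 and 3097 CPM in T cells. No test of the cause was made, and no MHC allele or haplotype was read.

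T cell receptor segments were read mostly as C segments in both libraries. Beta V segments had 11 UMIs beside 2969 of C segments in shCtrl, 0.369%, and 113 beside 24410 in shSrsf10, 0.461%. For alpha, V segments had 7 beside 539, 1.28%, and 146 beside 5159, 2.75%. Collagen and matrix genes in epithelial cells had a median of 0.46 (0.23 to 0.75), with 5 of 13 higher, 1 lower and 7 between, and Dcn, a matrix proteoglycan of fibroblasts, was at 2.98, while Fn1, fibronectin, was at -0.67.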
